A study of Homo sapiens with 8 samples.

How the data were processed

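Cells of a human embryonic kidney line were plated 24 h before treatment and RNA was prepared 4 h after it, per the labels' protocols. From 5 µg of total RNA per sample, antisense RNA was made by linear amplification with T7 RNA polymerase and labelled with the dye Cy3, so each array has 1 colour. Amplification from an oligo(dT) primer favours the 3′ ends of transcripts. The 8 samples fall into 4 treatments on 2 chips, with 1 array each. Treatment and chip were taken from the sample titles. The labels give no replicate, slide or date, so no batch could be examined.

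The deposited file of each array gives 1 spot intensity per probe on a linear scale, with no background value and no detection flag. The scanner, the image software and the background treatment are not given in the sources used here. Between 0 and 3 probes per array carry the text "not detected" in place of a number. These were taken as missing spots, and 39395 of 39400 probes with a value on all 4 arrays of their chip were kept. The share of values that are exact multiples of 0.5 differs between arrays. Whether some arrays were rescaled or averaged before deposit is not given in the sources used here.

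The deposited value table holds, for the same arrays, a score per probe. Set against the intensities, each column was a straight-line function of log2 intensity (r at least 0.999998): log2 intensity minus a median, divided by the median absolute deviation. For untreated, ligand and combined samples both were taken over chips A and B together, whereas each irradiated array was scaled alone. One score unit is thus a 1.41-fold to 1.59-fold difference, depending on the array. The column medians on chip A were 0.09 (untreated), -0.30 (ligand), 0 (radiation) and -0.41 (combined). On chip B they were -0.08, 0.19, 0 and 0.28. Direction is settled, since higher scores are brighter spots. Probes not detected carry scores of -35.64 to -23.22. This table served only as an alternative.

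Intensities were log2-transformed without background correction and quantile-normalized within each chip with limma 3.58.1 in R 4.3.3. As there is no detection flag, a probe counted as bright when its mean log2 intensity over the 4 arrays of its chip was above the chip's median. A probe was counted as higher or lower in a comparison at an absolute log2 difference of 1 or more. This is a rule of size and not a test. In addition, limma (lmFit, then eBayes with an intensity trend) was fitted per chip with additive terms for ligand and radiation. This leaves 1 residual degree of freedom per probe. Its p-values assume that no real interaction exists, measure only the spread between these arrays, and were adjusted by Benjamini-Hochberg over the 19697 bright probes of both chips. The 2 differences that measure the same agent on separate arrays were compared by correlation, with intervals from 1000 bootstrap draws of probes. Beside a share of probes in the same direction, the value for unrelated probes is the share of all bright probes of that chip that lie in that direction. The numbers of shared probes expected from independent lists were computed within each chip and summed. The number of arrays limits the precision of every value.

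The comparisons, the thresholds, the alternative settings and the rule for named probes were fixed before the data were examined. The rule took, among bright probes, the 8 highest and 8 lowest for the ligand and for radiation by the smaller of the 2 differences without and with the other agent, both at 1 log2 unit or more in the same direction. For the combined treatment it took the 6 highest and 6 lowest, and for the departure from additivity the 5 highest and 5 lowest. As probe IDs are not paired with genes in the files or the reference used here, the condition of 1 gene symbol could not be applied, and the first 2 in each direction are printed. For the same reason the gene lists fixed beforehand (damage response, repair, cell cycle, NF-kB, apoptosis and others) and the genes to be named always were not evaluated.

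The alternative settings fixed in this way were median scaling, cyclic loess, no filter on dim probes, the brightest 25% of probes, the deposited value table, 2 other variance priors in eBayes and leaving out each treatment in turn. Chosen after seeing the data were normexp on the intensity alone with an offset of 50, leaving out the irradiated array of chip A, and removing a running median of 51 probes along the order of probe IDs.

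The steps were tested on simulated arrays with the real mean levels, in which 200 probes were changed by a ligand effect common to both radiation states. The simulated scatter was Gaussian and equal for all probes and arrays of a chip. Its size came from the real departure from additivity (0.318 log2 units per array on chip A, 0.171 on chip B). Of the changed probes that stayed bright, limma called 22 of 38 at 2-fold, and all of 38 at 4-fold, 32 at 8-fold and 26 at 16-fold. It also called 10 of 19563 unchanged probes, 3 of them above a log2 level of 10. The rule of size passed 257 unchanged probes (1.31%) in the simulated comparison of ligand with untreated. The scatter of the real arrays was not equal. On chip A the spread (scaled median absolute deviation) of an array against the other 3 was 0.297 for the ligand and 0.439 for radiation. The simulated shares therefore check the steps and do not give the power of the fit on the real arrays. Figures were drawn with matplotlib 3.10.9.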

Results

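Gene expression was measured in a human embryonic kidney (HEK) cell line under 4 treatments: no treatment, a ligand that binds the minor groove of DNA at 50 µM, ionizing radiation at 2 Gy, and the ligand given 1 h before 2 Gy. RNA was taken after 4 h of incubation. According to the series title, the question was how the ligand modulates the response to radiation. The labels do not name the ligand. Each treatment was hybridised once on chip A and once on chip B of an oligonucleotide array set, which gave 8 arrays. The chips carry different probes, 19700 on each, so they are not replicates of one another, and n = 1 array per treatment for every probe. No pairwise difference below therefore has a replicate check or a p-value. The files do not pair probe IDs with genes, so results are given per probe, and the gene lists chosen for this study were not evaluated.

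Spot intensities were alike on 7 arrays and much lower on the eighth. On chip A the median intensity was 219 for untreated cells, 168 for the ligand, 34.5 for radiation and 166.5 for the combined treatment. On chip B it lay between 202 and 225. The irradiated array of chip A was also the only one on which 100% of the values were multiples of 0.5. That share ranged from 5.35% to 38.9% on the other arrays. After quantile normalization, the brighter 50% of the probes of each chip were kept, 9848 on chip A and 9849 on chip B. Over these probes, log2 intensities of different treatments correlated at r = 0.819 to 0.919 on chip A and at 0.870 to 0.919 on chip B. The lowest value was that between radiation and the combined treatment on chip A.

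**Figure D1:**
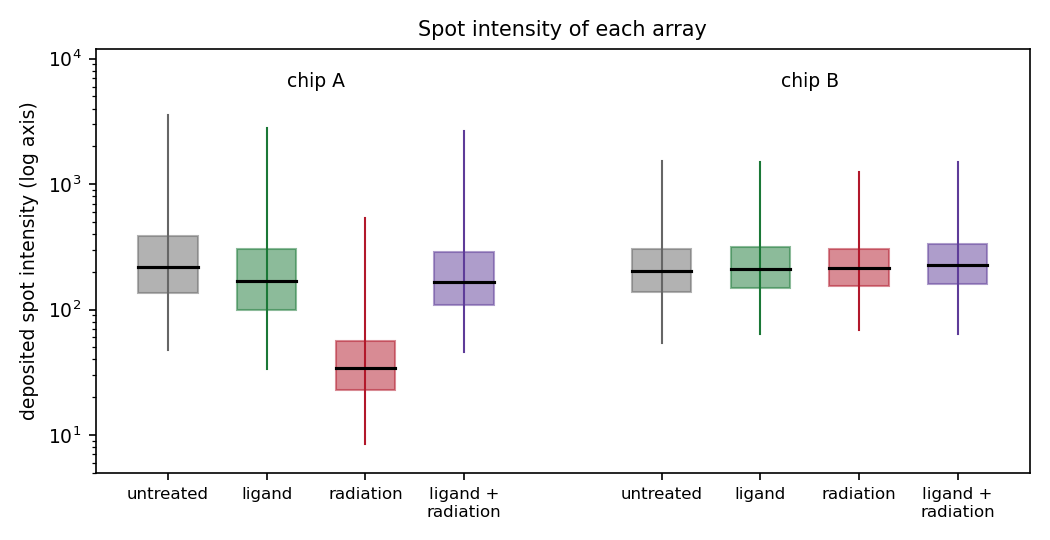
Deposited spot intensity (log axis) of the 4 arrays of each chip before normalization; boxes span the 25th to the 75th percentile, black lines mark the median and thin lines run from the 1st to the 99th percentile. The irradiated array of chip A has a median of 34.5, against 166.5 to 219 on the other arrays of that chip.

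Ligand treatment alone was compared with no treatment to ask what the ligand does without radiation. Of 19697 bright probes, 112 were at least 2-fold higher and 270 at least 2-fold lower in ligand-treated cells, 1.94% in all. The excess of lower probes was larger on chip B, with 13 higher and 136 lower, than on chip A, with 99 higher and 134 lower. On chip B, 93 of the 136 lower probes were at least 2-fold lower on the ligand array than on each of the other 3. In irradiated cells, where the combined treatment was set against radiation alone, 619 probes were at least 2-fold higher and 332 lower. Only 10 probes were higher and 10 lower by that margin in both ligand comparisons, and 37 went opposite ways, 34 of these on chip A and 3 on chip B. Independent lists within each chip would give 5.36, 4.52 and 11.6 probes. The probe obshum40K:A#02887 was higher by 1.46 log2 units without and 1.60 with radiation, and obshum40K:B#43509 by 1.41 and 1.35. The probe obshum40K:B#17913 was lower, at -3.18 without and -1.62 with radiation, as was obshum40K:B#42298, at -1.49 and -2.13. With arrays scaled to a common median, obshum40K:B#43509 was only 0.42 higher without radiation and obshum40K:B#17913 stood at -0.64 with radiation. Both are among the brightest spots, where few probes set the normalized value.

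Radiation alone was compared with no treatment to ask what 2 Gy does after 4 h. At least 2-fold differences numbered 742, with 231 probes higher and 511 lower in irradiated cells. Chip A held 674 of them and chip B 68, and the irradiated array of chip A was the dim one. In ligand-treated cells, where the combined treatment was set against the ligand alone, 419 probes were higher and 443 lower. The chips went opposite ways, with 258 higher and 422 lower on chip A and 161 higher and 21 lower on chip B. Of these 161 probes, 93 are those at least 2-fold lower on the ligand array of chip B than on every other array. The ligand array alone places them there. Under cyclic loess the majority over both chips turned (482 higher, 428 lower), as it did with normexp (465, 353) and the running median removed (412, 321). In both radiation comparisons 16 probes were higher and 32 lower, against 5.82 and 20.1 expected from independent lists within each chip, and 33 went opposite ways, against 21.9. Higher in both were obshum40K:A#09259, by 1.71 log2 units without and 1.47 with the ligand, and obshum40K:A#08505, by 1.56 and 1.37. The most negative measured differences in both were those of obshum40K:B#44251, at -3.80 without and -3.86 with the ligand. Its deposited intensity was 781 in untreated and 910 in ligand-treated cells, against 62 after radiation and 60.5 after the combined treatment. Only 0.528% and 0.817% of the spots of those arrays were dimmer, so the direction was measured but the size was not: with no background value, these spots cannot be told from the floor. The next, obshum40K:A#12896, was at -2.94 and -2.76, with 4.83% and 12.4% of the spots dimmer on the irradiated and combined arrays.

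The combined treatment gave 309 probes at least 2-fold higher and 288 lower than in untreated cells, 3.03% of the bright probes. Chip A accounted for 483 and chip B for 114. Against radiation alone 951 probes passed the same margin, 828 of them on chip A with its dim irradiated array. Against the ligand alone, a comparison without that array, 862 passed, 680 of them on chip A. The highest probe was obshum40K:B#29304, 6.76 log2 units above untreated cells, followed by obshum40K:A#06173 at 5.80. The former was the brightest spot of its array, where quantile normalization limits the value: it was 8.36 higher under median scaling and 8.61 under cyclic loess. In both, the combined array stood alone: obshum40K:A#06173 had a normalized log2 intensity of 12.13 there and of 6.12 to 6.36 on the other 3 arrays. The most negative measured differences were those of obshum40K:A#44367, at -7.57, and obshum40K:A#44558, at -6.48, where 2.78% and 9.03% of the spots of the combined array were dimmer, so these sizes too depend on a floor that was not measured. Here it was the untreated array that stood alone, since obshum40K:A#44367 was at 12.75 in untreated cells and at 5.18 to 6.26 under the other 3 treatments. Among the 43 probes that differed at least 8-fold between the combined treatment and no treatment, the combined array was at least 1.5 log2 units apart from every other array for 32 and the untreated array for 10. For the 12 such probes in the ligand comparison, the untreated array was the one apart for 10. For the 21 in the radiation comparison it was the untreated array for 10 and the irradiated array for 9. Chip A held 26 probes at least 8-fold brighter after the combined treatment than on each other array, and chip B 2. A probe can pass the brightness rule through such a high value on 1 array.

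**Figure D2:**
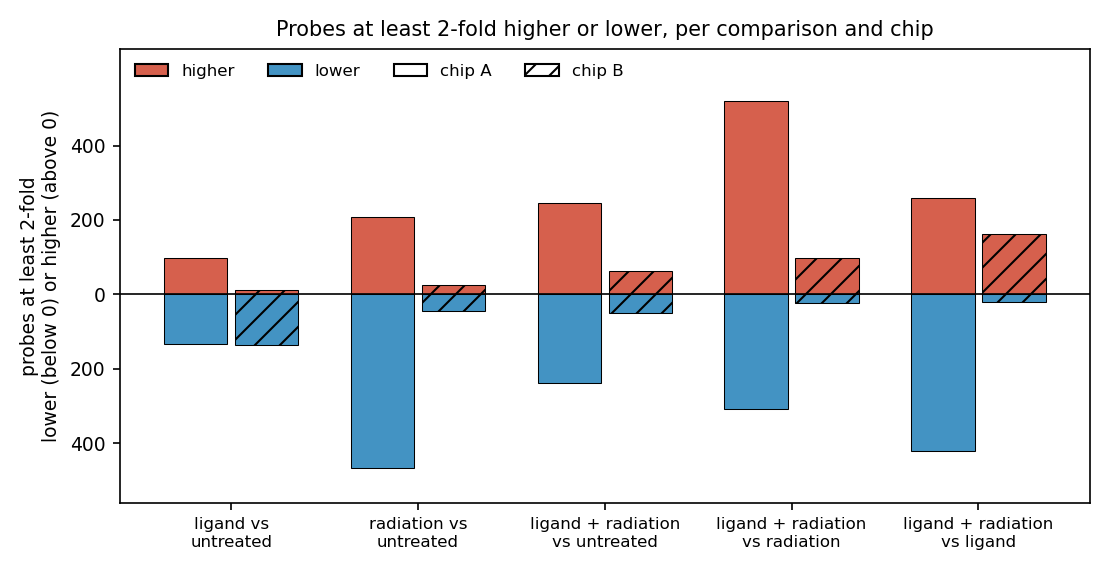
Number of bright probes at least 2-fold higher (red, above 0) or lower (blue, below 0) in each comparison, on chip A (plain bars, 9848 probes) and chip B (hatched bars, 9849 probes), with 1 array per treatment and chip. Chip A has more such probes than chip B in each of the 5 comparisons, with 674 against 68 for radiation.

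Whether the combined treatment differed from the sum of the single ones was measured as the radiation difference with the ligand minus that without it. This departure was at least 1 log2 unit for 1859 probes, 1108 above and 751 below 0. Chip A, with the dim irradiated array, held 1535 of them and chip B 324. On chip B 275 were above and 49 below 0. A low value on the ligand array alone, as for the 93 probes of chip B, raises the departure. The largest values were those of obshum40K:B#29304, at 6.78 (8.47 under median scaling, 8.28 under cyclic loess), and obshum40K:A#44367, at 6.50, both set by a single array as described above. The lowest were obshum40K:A#08305, at -4.90, and obshum40K:A#14805, at -4.86. The former was bright on the irradiated array alone, at 10.71 against 5.84 to 6.14. On the other arrays of the chip only 13.1% to 21.5% of the spots were dimmer. It passed the brightness rule only through the irradiated array, and its size depends on the floor. So does the size of obshum40K:A#14805, since 7.34% of the spots of the combined array were dimmer. The departure uses each of the 4 arrays once, so it has no error of its own. In the combined treatment the ligand preceded radiation by 1 h. Whichever agent the 4 h of incubation are counted from, at least 1 agent acted for a different time than when given alone. This too enters the departure.

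An additive model fitted with limma used the 2 arrays with and the 2 without each agent as repeats, and took the departure from additivity as error. For radiation 1 probe passed Benjamini-Hochberg adjustment over both chips: obshum40K:B#44251 fell to spots near the floor (measured log2 effect -3.83, SE 0.178, limma adjusted p = 0.0252), and was lower on both irradiated arrays than on either of the others. The next smallest adjusted p in limma was 0.368. Under median scaling its effect was -3.87 (SE 0.174) and its adjusted p in limma 0.0675, within a range of 0.00214 to 0.0675 over the settings in which it was tested. It was too dim for the brightest 25% of probes and, in the deposited value table, for the brighter 50%. For the ligand, limma called 0 probes, with a smallest adjusted p of 0.999. At an unadjusted p under 0.05 limma gave 467 probes for the ligand and 893 for radiation, against 985 expected by chance. For radiation this turned with the processing: 1229 probes passed under median scaling and 1002 with the running median along the probe order removed.

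The 2 × 2 layout measures each agent on separate pairs of arrays, which is the closest it comes to a repeat. The repeat is not exact, since exposure times in the combined treatment cannot all equal those of the single treatments. Across bright probes, which are not independent replicates, the ligand difference with radiation correlated with that without it at r = -0.150 on chip A (95% bootstrap interval over probes -0.179 to -0.124) and at -0.00187 on chip B (-0.0286 to 0.0243). For radiation with and without the ligand, r was 0.0300 on chip A (0.00993 to 0.0513) and 0.0829 on chip B (0.0496 to 0.119). Of the probes with a ligand difference of at least 2-fold without radiation, 39.5% of 233 on chip A and 67.8% of 149 on chip B lay in the same direction with it. Unrelated probes would give 50.6% and 55.0%. On chip B, 3 probes were higher and 6 lower in both ligand comparisons, against 0.131 and 0.331 expected from independent lists, and 3 went opposite ways, against 1.40. In both radiation comparisons of chip B, 2 were higher and 5 lower, against 0.392 and 0.0938, and 2 went opposite ways, against 0.770. Independent lists take all probes as equally variable, so probes with more scatter can exceed these numbers in any direction. With a running median along the order of probe IDs removed, the ligand share on chip B was 53.4% of 146 probes, against 49.7% for unrelated ones. For radiation the share in the same direction with the ligand was 54.3% of 674 on chip A and 66.2% of 68 on chip B, against 49.5% and 52.5% for unrelated probes. With the running median removed it was 51.8% on chip A (95% Wilson interval 48.0% to 55.6%) and 72.1% on chip B (59.8% to 81.8%), against 49.5% and 50.0%.

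**Figure D3:**
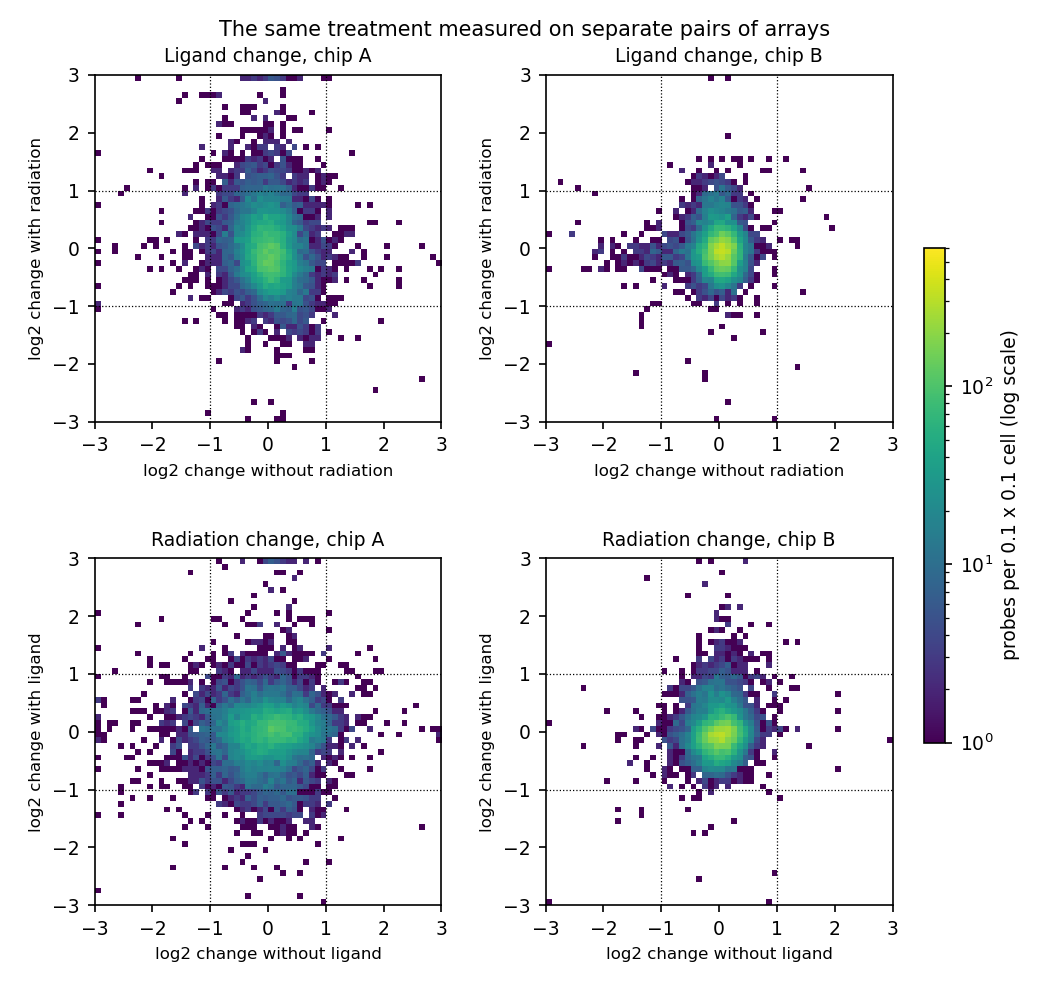
Log2 difference for the ligand (upper panels) and radiation (lower panels) without the other agent on the x axis and with it on the y axis, for bright probes of each chip; colour gives the number of probes per cell on a log scale, dotted lines mark 1 log2 unit, and values beyond 3 are drawn at the edge. Neither agent gives a diagonal cloud, with r between -0.150 and 0.0829 in the 4 panels.

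Comparisons that share the untreated array would be correlated through that array even if no treatment had an effect. The ligand and radiation differences from untreated cells correlated at 0.499 on chip A and 0.368 on chip B. Simulated unchanged arrays with equal scatter gave 0.490 and 0.488. The covariances were 0.120 on chip A and 0.0315 on chip B, against simulated values of 0.131 and 0.0461. The combined treatment correlated with the ligand at 0.359 and 0.315 (simulated 0.505 and 0.495), with covariances of 0.0818 and 0.0314 (simulated 0.136 and 0.0466). With radiation it correlated at 0.401 and 0.412 (simulated 0.503 and 0.491), with covariances of 0.130 and 0.0405 (simulated 0.135 and 0.0462). The simulated correlations follow from equal scatter by construction. The simulated covariances follow from the mean observed spread of these same 3 differences, so they are no separate check. If independent scatter acted alone, the 3 covariances of a chip would share 1 value, the variance of the untreated array. On neither chip were they all alike, and the cause was not tested. With 1 untreated array per chip, the controls could not be split.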

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

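The correlations and the count of departures from additivity belong to the comparisons fixed beforehand. Their use to weigh explanations and the other tests of this part were chosen after the results were seen, except the test of the levels of neighbouring probes. The intervals of this part take probes as independent draws, which they are not, and do not measure the spread between arrays.

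The ligand difference changed its balance with radiation: 29.3% of the probes at least 2-fold apart were higher with the ligand in unirradiated cells and 65.1% in irradiated cells. The shares went from 42.5% to 62.8% on chip A and from 8.72% to 80.5% on chip B. Every alternative in log2 units kept the turn, with 33.8% and 73.8% under median scaling and 27.6% and 70.8% under cyclic loess. In the deposited value table the shares were 16.8% without and 41.1% with radiation, so lower probes stayed in the majority. There 1 unit is less than 2-fold and columns are centred differently. The medians were 0 for radiation on both chips, and -0.41 (chip A) and 0.28 (chip B) for the combined treatment. On chip B, 93 of the 136 lower probes without radiation were lower on the ligand array than on every other array. For obshum40K:A#14805 the ligand difference was 2.65 log2 units without radiation and -2.21 with it. Only 7.34% of the spots of the combined array were dimmer, so the size of the latter depends on a floor that was not measured. The latter also uses the dim irradiated array. Neither difference was tested, as each rests on 1 array per treatment and chip. On chip A, a ligand change common to both radiation states is argued against as the main content by a covariance of -0.0387 between the 2 ligand differences (95% bootstrap interval -0.0457 to -0.0326), a value that rests on the dim irradiated array; scatter of each array alone leaves r = -0.150 (-0.179 to -0.124) unaccounted for. On chip B a common change stays open, with a covariance of -0.000189 (-0.00290 to 0.00250), and over all bright probes scatter alone may account for r = -0.00187. For the chip B probes at least 2-fold apart, scatter alone is not settled: 67.8% (95% Wilson interval 59.9% to 74.8%) went the same way with radiation, above the 55.0% of unrelated probes, but 53.4% (45.3% to 61.3%) against 49.7% once a running median along the probe order was removed. Before that removal, 3 were higher and 6 lower in both ligand comparisons, against 0.131 and 0.331 expected from independent lists. Another 3 went opposite ways, against 1.40. Whether the 1859 probes at 1 log2 unit or more from additivity hold a real joint response cannot be told apart from array scatter, since no treatment has a second array. The unequal exposure times of the combined treatment also enter these values.

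On the ligand array of chip B, 93 bright probes lay at least 2-fold below each of the other 3 arrays and 2 lay above. A fault that follows the order of the probes is a candidate explanation: 18 pairs of these probes stood within 5 places of each other by ID, against at most 8 in 1000 random draws. Related genes placed next to each other may also give such pairs. Levels within a close pair differed on the other arrays by 0.390 log2 units on average, against 0.521 to 1.45 for random pairs of the set. Both explanations stay open, and a response of related genes to the ligand alone is untested because the ligand array has no repeat.

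The irradiated array of chip A gave 674 probes at least 2-fold from untreated, against 68 on chip B. Chip A also held more in comparisons without that array. It had 233 against 149 for the ligand, 483 against 114 for the combined treatment, and 680 against 182 for the combined treatment against the ligand. With that array left out, the last 2 comparisons gave 621 and 891 over both chips, against 597 and 862 with it. That array thus does not account for the whole excess of chip A. Scatter of dim spots stays open as a cause. That array's spread was 1.33 times that of the others (95% bootstrap interval 1.25 to 1.41) among the brightest 25% of the bright probes. This cannot decide, because these probes were ranked by mean level over all arrays of the chip and may still be dim on that array. There the 75th percentile of intensity was 56.5, below the 25th percentiles of 98.6 to 134.6 on the other arrays of chip A. A radiation change common to both ligand states is argued against as the source of most of the set, which would need at least 75% of these probes to move the same way with the ligand (a limit set after the data were seen): 54.3% did (95% Wilson interval 50.5% to 58.0%). For a small part of the set it stays open, since unrelated probes give 49.5%. A common factor for all spots of an array drops out in quantile normalization and cannot give this excess. Rescaling of another kind that the other arrays received and this one did not cannot be told apart from a poor hybridisation. On this array 100% of the values are multiples of 0.5, and whether or how the others were rescaled is not given in the sources used here.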

How the results depend on the processing

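The background alternative was not run because the files hold no background column, and gene-list alternatives were not run because probes are not paired with genes. Normexp, the running median and leaving out the irradiated array of chip A were chosen after seeing the data. Without the brightness filter, 976 (ligand), 1781 (radiation) and 1652 (combined) probes were 2-fold from untreated, 2324 (combined) from radiation and 1943 from the ligand, 4588 departed from additivity, and the ligand agreement was r = -0.0731 (-0.108 with the filter). In the brightest 25% these counts were 220, 451, 360, 617, 529 and 1036, and limma called 0 probes for radiation. These settings test more or fewer probes by construction, but the counts did not move in proportion to the number tested, and the cause was not tested. Under median scaling limma also called 0 for radiation, and the cause was not tested. In the deposited value table, where 1 unit is less than 2-fold and columns are centred differently, the counts were 1563, 2720, 3300, 3329, 2479 and 4686, limma called 1 probe for the ligand and 3 for radiation, and the ligand agreement was -0.0830. Without the irradiated array of chip A, 68 probes were 2-fold from untreated for radiation, 123 for the combined treatment from radiation, 324 departed from additivity, and the agreement was -0.00187 for the ligand and 0.0829 for radiation, since only chip B remained. Leaving out 1 treatment left no residual degrees of freedom and no test, and only 1 pairwise difference per agent. The counts at 1 log2 unit or more were therefore those of comparisons already given: 382 or 951 for the ligand and 742 or 862 for radiation. The additive effects, each a mean of 2 such differences, numbered 187 and 286 with all arrays. Leaving out a treatment is thus no separate check of them. No paired analysis was possible because each treatment has 1 array per chip.

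Cyclic loess, normexp, the running median and both other variance priors kept every count within 1.5 times. Among the pairwise comparisons and the departure, the share of higher probes moved by over 10 points under median scaling for radiation (162 higher, 622 lower, against 231 and 511), and in the deposited table for the ligand (263, 1300), the combined treatment (1025, 2275) and the combined treatment against radiation (1368, 1961). It also moved for radiation without the brightness filter (749, 1032), and without the irradiated array of chip A for the combined treatment against radiation (99, 24, from 65.1% to 80.5% higher) and the departure (275, 49, from 59.6% to 84.9%). For additive radiation effects of 1 log2 unit or more, 49.7% were higher. This became 34.6% under median scaling, 35.7% in the deposited table and 70.8% without that array. For the ligand 61.5% became 32.5% in the deposited table, 51.4% with normexp and 26.0% without that array. Of 96 log2 values of printed probes under 4 alternatives, 92 kept direction and stayed at 1 log2 unit or more, 4 fell under 1 log2 unit and 0 turned. These probes were picked for large differences on the same arrays, which favours this outcome. All 24 score differences of these probes in the deposited table kept their direction.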

Other observations

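The values in this part were computed after the data had been seen and carry no explanation.

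The 86 bright probes of chip A that lay at least 2-fold above every other array after the combined treatment held 12 pairs within 5 places of each other by probe ID, against a mean of 1.92 and at most 6 in 1000 random draws. The 155 probes that were lowest on the irradiated array of chip A held 7 such pairs, against a mean of 6.17.

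The deviation of an array from the mean of the other 3 arrays of its chip, limited to 1.5 log2 units, correlated between neighbouring probe IDs for all 8 arrays. A pattern on 1 array also enters the deviations of the others through that mean. A small correlation therefore does not show that the array itself holds a pattern. Averaged over distances of 1 to 10 places, the correlation was 0.186 on the combined array and 0.1004 on the irradiated array of chip B. It ranged from 0.0308 to 0.0553 on the other 6 arrays. The highest of 100 shuffles of each array was at most 0.00700. The mean level itself correlated between neighbours at 0.0512 on chip A and 0.0420 on chip B.

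On chip A, the 892 bright probes with IDs from 40000 to 44999 had a median radiation difference of 0.24 log2 units, and in the other ID ranges the median lay between -0.05 and 0.10.

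On the untreated array of chip B, values that are multiples of 0.5 were higher relative to the other arrays of the chip than other values of like brightness, by a median of 0.17 log2 units, in each of 10 intensity bins. The irradiated array of chip B also had them higher in each of the 10 bins, by a median of 0.09. On the other 5 arrays with both kinds of value the median difference ran from -0.17, on the ligand array of chip A, to -0.01.

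The spot of obshum40K:B#29304 had a deposited intensity of 135556 after the combined treatment and of 337 to 414 otherwise. No other value on the 8 arrays was above 38953.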
